A study of Schizosaccharomyces pombe with 15 samples.

How the data were processed

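The data are peak lists from chromatin immunoprecipitation sequencing of fission yeast (Schizosaccharomyces pombe) with an antibody against the FLAG tag. Per the labels' protocols, cells were grown at 32 °C in rich medium, moved to 18 °C for 2 hours and fixed there with formaldehyde for 30 min, and lysates were kept with antibody-coated beads for 3 hours. Atf1, Pcr1 and Deb1 carried 3 copies of the FLAG tag and Orc1 carried 5, per the labels. There were 15 samples in 8 groups, taken from the sample titles, and 4 lists, 1 for each of Atf1, Pcr1, Deb1 and Orc1.

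The submitters' processing notes name Bowtie 1.2.3, MACS2 2.1.2 and bedtools with no order or settings; the genome build is not given in the sources used here. The labels name the untagged sample together with the Atf1 list and the input samples together with the Deb1 and Orc1 lists, and do not say how the controls were used. Each deposited list gives, per peak, the fold enrichment (a ratio over the control at the summit), the −log10 of the caller's p-value and q-value, a score and the offset of the summit. The score in the deposited lists was 10 times the −log10 q, rounded down to a whole number, for all 1995, 1567, 351 and 1526 records. These values are the authors' and were used only to describe, rank or filter peaks within a list.

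The lists show signs of a step after peak calling. The numbers in the peak names had gaps, with 70.7%, 74.3%, 21.1% and 66.6% of the numbers up to the highest present for Atf1, Pcr1, Deb1 and Orc1. In 129, 113, 93 and 109 peaks the summit offset pointed outside the interval, and 7, 10, 0 and 7 names were used more than once. Intervals thus appear trimmed, and if so each fold may be that of the peak as called before trimming. The names carry the label of 1 library per list. The summit was taken as the interval's start plus the offset where this fell inside the interval, and as the midpoint otherwise. No 2 records of a list overlapped, so merging left the numbers of peaks as deposited.

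The reference was the RefSeq genome and annotation of assembly ASM294v3. Its chromosome 2 is 4539804 bp long, and the lists hold peaks up to 4551989, at least 12185 bp further. A scan for the ATF/CRE core within 40 bp of Atf1 and Pcr1 summits of fold at least 2.5 placed it at 20.1% of summits on chromosome 1, 21.6% on chromosome 2 left of 2110000 and 20.7% on chromosome 3 with no shift. Right of 2160000 on chromosome 2 the share was 1.22% with no shift and 24.1% at a shift of 12220 bp. No peak or gene coordinate was converted. Genes and sequence were used only on chromosomes 1 and 3 and on chromosome 2 left of 2110000, called the annotated part, which holds 1609 Atf1, 1269 Pcr1, 296 Deb1 and 1219 Orc1 summits; overlaps between lists used the whole genome. The mating-type region was taken in the lists' coordinates from the annotated start of mat1 to 5000 bp beyond the annotated end of mat3, moved by the 12185 bp that the lists extend further, which serves only to bound the region.

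Peaks counted as shared when they overlapped by at least 1 bp. The expected number came from 10000 random placements of the second list within its chromosomes with widths kept, one-sided, and p-values were adjusted by Benjamini-Hochberg over the 6 pairs. Places of all 4 proteins were merged regions with a peak of each list, against placements of Deb1 and Orc1. Positions relative to genes, the motif and AT content were compared with 10000 random draws per chromosome, two-sided except for the motif; motif, word and AT windows were 100, 50 and 150 bp. Intergenic positions are those outside protein-coding genes, which may hold non-coding genes. Intergenic placement put every midpoint of the placed peaks there, although coding sequence held 31.1% of Atf1, 26.0% of Pcr1 and 17.6% of Orc1 summits. It may thus expect too much sharing, and its ratios may be too low. The Deb1 word of 7 bases was chosen on chromosome 1 and tested on chromosomes 2 and 3 with Fisher's exact test. The gene lists, 12 in number, were tested with Fisher's exact test and adjusted over 48 tests against 4090 protein-coding genes (tRNA genes against other non-coding genes); genes that share a divergent promoter were counted each, which makes these p-values too small. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting error only. With 1 list per protein there is no replicate, p-values describe these lists, and depth per sample is unknown.

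The groups, tests, gene lists, all other alternatives than those named at the end and the rule for named genes were chosen before the data were examined. The rule took the 10 peaks of highest fold of each list with the gene whose annotated start is nearest, every peak of the mating-type region, up to 4 bound members of each gene list in order of fold, the genes atf1, pcr1, deb1 and orc1 to orc6, and up to 10 places of all 4 proteins in order of Deb1 fold. The nearest gene was taken among protein-coding genes, a restriction added after the data were seen, since non-coding genes are annotated at most places. Of the genes this rule names, 1 is not reported here.

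On simulated lists placed at random, 3.00% of 100 overlap tests of Deb1 with Atf1 gave p under 0.05, with a mean ratio of 0.977. With 30% of the Deb1 peaks planted on Atf1 peaks, 100.03% of the planted and chance overlaps were found, and all 20 lists passed. A share test with no effect passed in 6.00% of 200 runs of the Deb1 list size, and a test at 3 times the background passed in all of 50. A word planted in 15% of windows of the size of the Deb1 chromosome 1 set was found in all 20 runs. The overlap and share simulations used the same random model as their tests. They check the computation, not how the tests behave on clustered or intergenic peaks. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Alternatives covered stricter caller thresholds, other overlap rules, random placements, windows, motifs, word lengths, backgrounds, gene assignments and the removal of repeats and chromosome ends (within 50 kb); interval midpoints, summits inside their interval only, placement on the annotated part and the removal of repeats for motif, words, AT content and gene lists were chosen after seeing the data.

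Further tests were chosen after seeing the data. Long terminal repeats, Tf2, tRNA and rRNA genes of the annotation were counted as touched when a peak overlapped them, against 10000 placements. Shares of peaks with a sequence were compared between peaks with and without a peak of another list by Fisher's exact test, two-sided (12 tests, adjusted together). The word AGGTAAC was counted over whole Deb1 intervals, and copies of a repeat were told apart by the share of their 36-base words found elsewhere in the reference, with at most 10% taken as few. The Atf1 samples with s1 and s2 deleted and the untagged sample are not analysed here as lists of their own, and the inputs were not analysed here on their own.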

Results

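Chromatin immunoprecipitation followed by sequencing was used to map where Atf1, Pcr1, Deb1 and Orc1 sit on the chromosomes of fission yeast. Atf1 and Pcr1 are bZIP transcription factors of the ATF/CREB family that bind DNA as a heterodimer. Deb1 is a DNA-binding protein, and Orc1 is a subunit of the origin recognition complex (ORC), which marks the sites where DNA replication starts. Each protein carried a FLAG epitope tag at its own gene and was precipitated with an antibody against FLAG. The 15 samples fall into 8 groups: 2 precipitations each for Atf1, Pcr1, Deb1 and Orc1, 2 input samples each for the Deb1 and Orc1 strains, 2 precipitations of Atf1 from cells labelled as lacking the sites s1 and s2, and 1 precipitation from an untagged strain. The cells were kept for 2 hours at 18 °C before fixation. The series asks, by its title, about a composite DNA element needed to inherit heterochromatin, and by its design text about the genomic localization of these proteins. The files used here hold 1 peak list per protein, so no list has a replicate beside it, and read depth per sample is unknown. The s1 and s2 deletion samples and the untagged sample have no list of their own and are not analysed here as separate samples.

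The lists held 1995 peaks for Atf1, 1567 for Pcr1, 351 for Deb1 and 1526 for Orc1. The median fold enrichment, the value given to each peak by the authors' caller, was 2.25 for Atf1, 2.41 for Pcr1, 4.35 for Deb1 and 2.21 for Orc1. The highest Atf1 peaks lay next to SPAC186.03 (5.90-fold, chromosome 1, 5534283 to 5535074), svf1 (5.87-fold), nhp6 (5.78-fold), which encodes a high-mobility-group protein, and pqr1 (5.77-fold). The highest Pcr1 peak was in an intron of cds1, the replication checkpoint kinase (6.82-fold, chromosome 3, 740128 to 741286), followed by peaks upstream of pqr1 (6.68-fold), gut2 (6.60-fold), osh6 (6.48-fold) and srk1 (6.45-fold), a kinase of the stress response. Other Pcr1 peaks among the 10 of highest fold were nearest to atf21, SPAC110.06 and SPAC16A10.01, and 1 lay on chromosome 2 at 2277154 to 2277500. For Atf1 they were nearest to gut2, cds1 and mug143, with 3 more on chromosome 2 starting at 3167236, 2673234 and 2276903. The Deb1 peak of highest fold covered the start of brl2, a ubiquitin ligase gene (7.68-fold, chromosome 3, 488947 to 489795), and the next were near iec5 (7.18-fold), SPAC22E12.02 (7.17-fold), the retrotransposon Tf2-8 (7.11-fold) and aur1 (7.09-fold). Tf2-5, Tf2-4, SPBC36.02C, SPAC1705.02 and a place on chromosome 2 at 4449479 to 4450142 completed the 10. The Orc1 peak of highest fold was upstream of alr2 (6.54-fold, chromosome 2, 107357 to 108024), then hsr1 (5.57-fold), amt1, with 2 peaks (5.31-fold and 5.22-fold), and meu27 (5.26-fold). The others were nearest to oca2, ubr11, cys11 and car1, and 1 was on chromosome 2 at 4119524 to 4120249. Counting non-coding genes too, the peak near meu27 was nearest to SPCTRNAVAL.12 (11 bp) and the one near ubr11 to SPATRNACYS.03 (24 bp). A caller −log10 q of at least 10 left 758 Atf1, 630 Pcr1 and 871 Orc1 peaks, while 349 of the Deb1 peaks passed it. A fold of at least 3 left 416, 447, 287 and 279 peaks for Atf1, Pcr1, Deb1 and Orc1. Leaving out repeats and chromosome ends left 208 Deb1 peaks.

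Atf1 and Pcr1 were compared because they bind DNA together, and they were found at largely shared places. Of the 1995 Atf1 peaks, 1219 (61.1%, 95% interval 58.9 to 63.2) overlapped a Pcr1 peak, and 1257 of the 1567 Pcr1 peaks (80.2%) overlapped an Atf1 peak. Among the 10 peaks of highest fold in the Atf1 list, which include svf1, nhp6 and cds1, each overlapped a Pcr1 peak. Random placement of the Pcr1 peaks gave 174.2 ± 12.4 shared Atf1 peaks (SD of the placements). The observed number was 7.0 times the expected one (n = 1995, adjusted p = 0.0001, the smallest that 10000 placements can give). Placing peaks only among intergenic positions lowered the ratio to 3.74 on the annotated part of the genome (n = 1609, adjusted p = 0.00015).

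**Figure D1:**
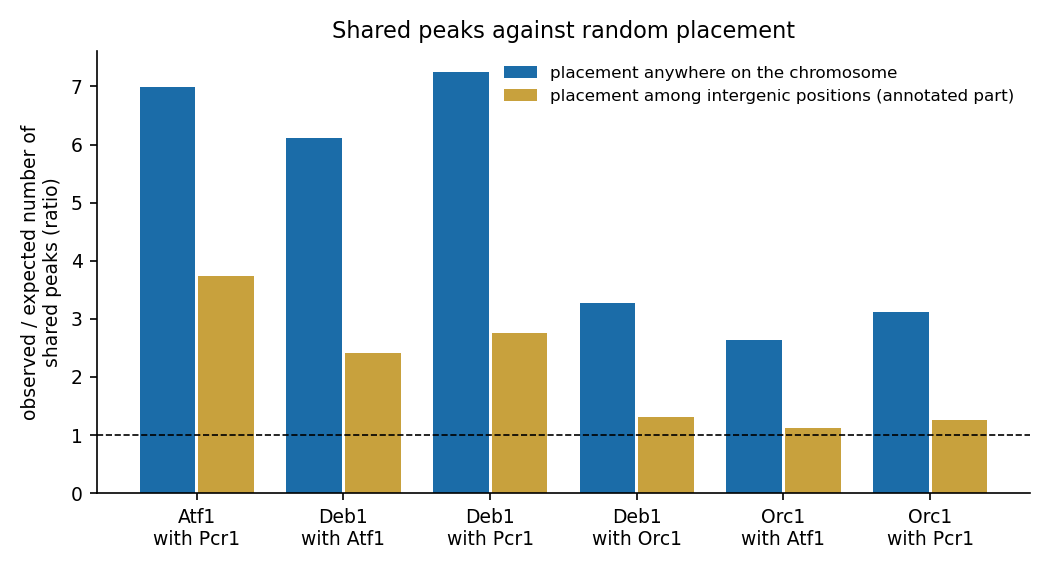
Ratio of observed to expected shared peaks for the 6 pairs of lists (horizontal axis) on a linear scale starting at 0, with the dashed line at a ratio of 1. Blue bars stand for random placement anywhere on a chromosome and yellow bars for placement among intergenic positions of the annotated part; the ratios of Deb1 with Pcr1 were 7.25 and 2.76, and those of Orc1 with Atf1 were 2.63 and 1.13.

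Sharing rose with the height of the peak. Peaks were split into 4 bins by fold. In the highest bin of Atf1 peaks, 481 of 498 (96.6%) overlapped a Pcr1 peak, against 125 of 498 (25.1%) in the lowest bin (Fisher's exact test, two-sided, p = 9.47e-137). The Pcr1 list gave 382 of 391 peaks (97.7%) with an Atf1 peak in its highest bin and 232 of 391 (59.3%) in its lowest (exact p = 1.39e-44).

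The core of the ATF/CRE motif, TGACGT, which Atf1 and Pcr1 are known to bind, stood within 100 bp of 257 of 1609 Atf1 summits (16.0%, 95% interval 14.2 to 17.9) and of 181 of 1269 Pcr1 summits (14.3%, 12.4 to 16.3). Random intergenic positions held it in 3.16% and 3.14% of draws, giving ratios of 5.06 for Atf1 (n = 1609) and 4.55 for Pcr1 (n = 1269, adjusted p = 0.0002 for each). The highest of 4 bins of Atf1 peaks by fold carried the motif at 32.1% of summits and the lowest at 9.93%; for Pcr1 these shares were 31.9% and 6.29%. Deb1 summits held the motif in 6.08% of cases (n = 296, ratio 1.92, adjusted p = 0.0101) and Orc1 summits in 4.10% (n = 1219, ratio 1.31, adjusted p = 0.0357). The Orc1 call was lost with the palindrome TGACGTCA (n = 1219, ratio 1.87, adjusted p = 0.166), with a window of 250 bp (1.00, 0.504) and at a −log10 q of at least 10 (1.07, 0.404). The Deb1 call was lost with a window of 50 bp (n = 296, ratio 1.82, adjusted p = 0.0655). The Deb1 ratio rose to 3.20 without repeats and chromosome ends (n = 159, adjusted p = 0.000133) and to 7.99 with the palindrome, held by 4 of 296 summits (n = 296, adjusted p = 0.00227). Over the alternatives the ratio ranged from 2.67 to 8.49 for Atf1 and from 2.42 to 9.12 for Pcr1, each past the threshold.

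**Figure D2:**
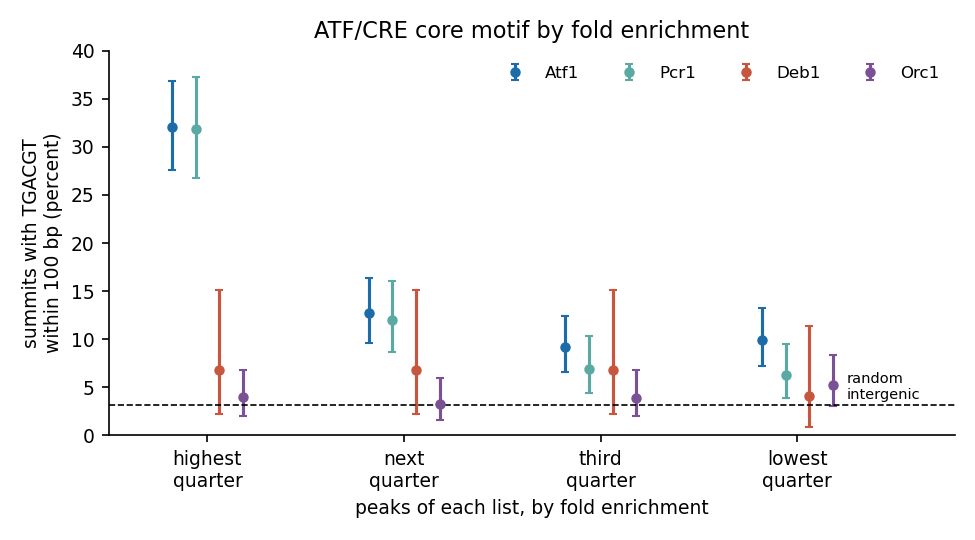
Percent of summits with TGACGT within 100 bp (vertical axis) for the 4 lists, each divided into 4 bins by fold enrichment (horizontal axis). Points are shares, bars are exact 95% binomial intervals and the dashed line is the mean share at random intergenic positions; the highest bins of Atf1 (32.1%) and Pcr1 (31.9%) stand above the rest.

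Deb1 was compared with the other lists because the series maps these proteins together. Most of its peaks overlapped an Atf1 peak, and most a Pcr1 peak, by at least 1 bp. Of the 351 Deb1 peaks, 264 (75.2%, 95% interval 70.4 to 79.6) overlapped an Atf1 peak, 244 (69.5%, 64.4 to 74.3) a Pcr1 peak and 115 (32.8%, 27.9 to 37.9) an Orc1 peak. The Deb1 peaks at brl2, iec5, SPAC22E12.02, Tf2-8 and aur1 each overlapped both an Atf1 and a Pcr1 peak, and of these only the one at iec5 also overlapped an Orc1 peak. Random placement gave ratios of 6.11 for Atf1, 7.25 for Pcr1 and 3.28 for Orc1 (n = 351, adjusted p = 0.0001 for each, the smallest the placements can give). With placement among intergenic positions (n = 296) the ratios were 2.41, 2.76 and 1.31, with adjusted p of 0.00015, 0.00015 and 0.0012. With summits required to lie within 100 bp, fewer of the 351 Deb1 peaks were shared: 152 with Atf1, 152 with Pcr1 and 60 with Orc1.

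Orc1 shared part of its places with the bZIP factors. Of the 1526 Orc1 peaks, 481 (31.5%, 95% interval 29.2 to 33.9) overlapped an Atf1 peak and 441 (28.9%, 26.6 to 31.2) a Pcr1 peak. The Orc1 peaks at alr2, hsr1, meu27 and oca2 overlapped both. The 2 highest peaks upstream of amt1, an ammonium transporter gene, and the peak at cys11 overlapped neither. The ratios to random placement were 2.63 for Atf1 and 3.11 for Pcr1 (n = 1526, adjusted p = 0.0001 for each). Intergenic placement left ratios of 1.13 for Atf1 (n = 1219, adjusted p = 0.0012) and 1.27 for Pcr1 (adjusted p = 0.00015). It placed all Atf1 and Pcr1 peaks among intergenic positions, whereas coding sequence held 31.1% and 26.0% of their summits. These ratios may thus be too low, and how much sharing follows from intergenic preference is not decided.

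The title of the series speaks of a composite element, so places with all 4 proteins were counted. At 96 places a merged region held peaks of all 4 proteins, which need not all overlap each other. With a summit of each other list within 250 bp of the Deb1 summit the number was 63 (ratio 70.8). It was 56 at a −log10 q of at least 10 (ratio 21.0) and 60 without chromosome ends and the repeats of the annotated part (ratio 29.0). In order of Deb1 fold, the first of the 96 were upstream of iec5 (Deb1 7.18-fold, chromosome 1, 3321197 to 3322009), at 4449479 to 4450142 on chromosome 2, near SPBC36.02C (6.92-fold), and at 2648730 to 2649466 on chromosome 2. They were followed by places near mug51 (6.57-fold), vma21 (6.34-fold), alr2 (6.28-fold), SPBPB10D8.06C (6.25-fold) and hsr1 (6.25-fold), with a further place on chromosome 2 at 3500138 to 3502211 (6.32-fold). The promoter of atf1 itself was another (chromosome 2, 1545566 to 1546936), with folds of 3.04 for Atf1, 4.86 for Pcr1, 5.52 for Deb1 and 4.03 for Orc1. A place in the mating-type region was also among them. Random placement of the Deb1 and Orc1 peaks gave 6.60 ± 2.51 such places, a ratio of 14.5 (n = 96, p = 0.0001, the smallest the placements can give). Intergenic placement on the annotated part gave a ratio of 2.94 (n = 80, p = 0.0001). Both placements also break the overlaps of Deb1 and Orc1 with the other lists and with each other. The ratios thus do not show sharing by all 4 proteins beyond that of the pairs.

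The mating-type region of chromosome 2 holds the mat1, mat2 and mat3 cassettes, and only part of it is heterochromatin. In the coordinates of the deposited lists it was taken from 2114219 to 2150579, and it held 13 Atf1, 11 Pcr1, 19 Orc1 peaks and 1 Deb1 peak. The highest Atf1 and Pcr1 peaks of the region coincided at 2135545 to 2136217 (Atf1 4.71-fold, rank 65 of 1995) and 2135534 to 2136195 (Pcr1 4.69-fold, rank 124 of 1567). Further pairs lay at 2142722 to 2143744 (Atf1 3.89-fold) with 2143070 to 2143517 (Pcr1 4.43-fold), at 2143904 to 2144816 (Atf1 3.92-fold) with 2144230 to 2144760 (Pcr1 4.01-fold), and at 2133282 to 2133658 (Atf1 3.33-fold) with 2133360 to 2133596 (Pcr1 3.29-fold). The Deb1 peak, at 2144427 to 2144740, had a fold of 5.94 (rank 54 of 351) and fell inside the Atf1 peak that starts at 2143904. An Orc1 peak at 2144536 to 2144831 (2.46-fold) overlapped it. The remaining Atf1 and Pcr1 peaks had folds of 1.85 to 2.66 and 2.05 to 2.42. The 3 highest Orc1 peaks of the region, at 2117605 to 2117967, 2133525 to 2133998 and 2148958 to 2149634, each had a fold of 2.82, and the lowest had 1.34. Those 3 peaks also had the same −log10 q (21.6) and rank (354 of 1526). The Orc1 peaks starting at 2136009 and 2145766 likewise shared a fold of 1.93 and a −log10 q of 6.64. Whether such peaks are copies of 1 sequence that share reads was not tested, so the number and density of separate Orc1 peaks are uncertain. The density of peaks was 35.8, 30.3, 2.75 and 52.3 per 100 kb for Atf1, Pcr1, Deb1 and Orc1 in the region, against 15.9, 12.5, 2.79 and 12.1 over the genome, a comparison with no test. At a −log10 q of at least 10, 5 Atf1, 4 Pcr1, 1 Deb1 and 7 Orc1 peaks of the region were left. The tagged Atf1 and Pcr1 strains carry tet operators in place of the cenH repeat, so that peaks there were not read as presence or absence.

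**Figure D3:**
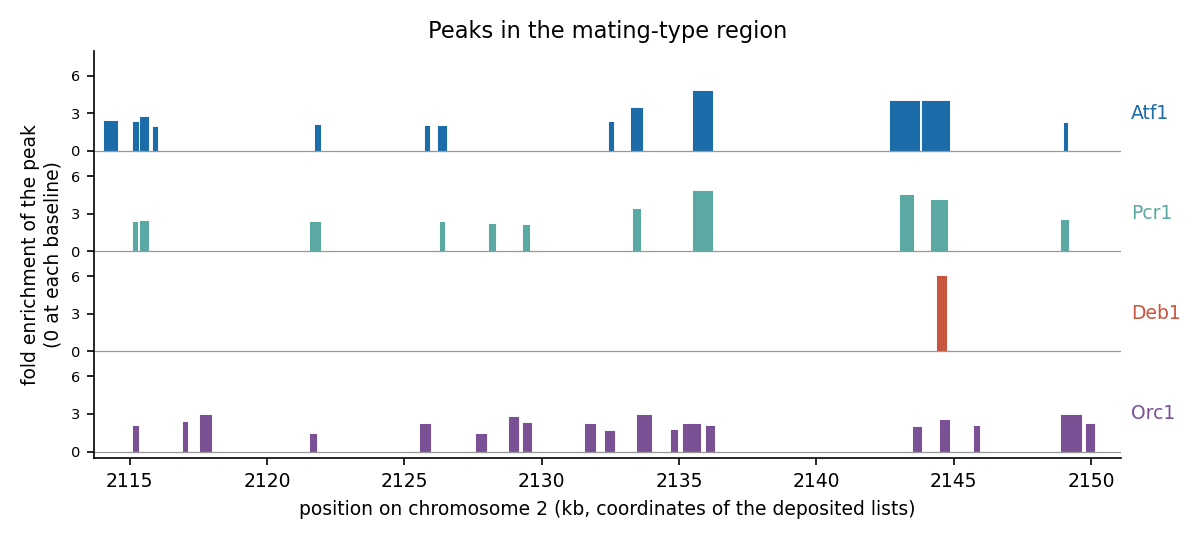
Map of the mating-type region, with the position on chromosome 2 in kb of the deposited coordinates on the horizontal axis and the caller's fold enrichment of each peak on the vertical axis, drawn from a baseline of 0 for each of the 4 lists. Each bar spans 1 peak; the only Deb1 bar (5.94-fold) lies where an Atf1, a Pcr1 and an Orc1 bar also lie.

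Summits of all 4 proteins lay mostly outside coding sequence. The promoter window, from 1000 bp upstream to 200 bp downstream of the start of a protein-coding gene, held 61.0% of 1609 Atf1 summits, 61.5% of 1269 Pcr1 summits, 74.0% of 296 Deb1 summits and 52.0% of 1219 Orc1 summits, where random placement gave 39.97%, 39.9%, 39.7% and 40.03%. Coding sequence held 31.1% of Atf1, 26.0% of Pcr1, 8.45% of Deb1 and 17.6% of Orc1 summits, against 56.4%, 56.3%, 55.9% and 56.5% at random. Places annotated only with a non-coding gene held 32.8% of Atf1, 37.0% of Pcr1, 36.8% of Deb1 and 44.1% of Orc1 summits, against 12.96%, 13.03%, 13.2% and 12.9% at random. All of these differences had an adjusted p of 0.000229, the smallest the placements gave after adjustment over 24 tests.

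The word found most in excess near Deb1 summits of chromosome 1 was GGTAACA, present within 50 bp of 17 of 138 summits (12.3%) and of 1.62% of intergenic windows. On chromosomes 2 and 3, which had no part in choosing it, the word stood near 25 of 158 Deb1 summits (15.8%, 95% interval 10.5 to 22.5), against 1.41% of 10000 intergenic windows (ratio 11.2). Summits of the other lists held it in 2.52% of cases for Atf1, 2.85% for Pcr1 and 1.22% for Orc1. Long terminal repeats, touched by 98 of 296 Deb1 peaks, are repeats that occur on several chromosomes, so these summits are not independent and no p-value is given for them. With repeats and chromosome ends left out of the test, GGTAACA stood near 16 of 76 Deb1 summits of chromosomes 2 and 3 (21.1%, ratio 14.9, Fisher's exact test, one-sided, p = 2.7e-14). The other lists then held it in 1.69%, 1.67% and 0.685% of cases (exact p = 3.61e-10, 1.08e-09 and 8.16e-12 against Deb1). With only the summits inside their interval the search chose another word, TATCTGA, which was not past the threshold on the held-out chromosomes (ratio 2.29, exact p = 0.0708). With repeats and chromosome ends left out of the search as well, it chose TCCCGAA (3 of 76 summits, ratio 6.93, exact p = 0.0104). GGTAACA and AGGTAAC were among the next words of that search.

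The sequence around Atf1, Pcr1 and Deb1 summits was less AT-rich than intergenic sequence. Within 150 bp, the AT content averaged 61.8% ± 5.41 (SD, n = 1609 summits) for Atf1, 61.9% ± 5.37 (n = 1269) for Pcr1 and 63.1% ± 5.22 (n = 296) for Deb1. The differences from random intergenic positions were -6.18, -6.14 and -4.81 points. Not all summits are intergenic: coding sequence held 31.1% of Atf1, 26.0% of Pcr1 and 8.45% of Deb1 summits. Intergenic summits alone were not compared, so position may make up part of these differences. Against whole chromosomes the differences were smaller, -2.08, -2.05 and -0.767 points (n = 1609, 1269 and 296, adjusted p = 0.000267, 0.000267 and 0.0134). Without repeats and chromosome ends the Deb1 difference from intergenic positions was -7.34 points (n = 159). Orc1 summits, of interest because fission yeast origins are AT-rich, had the highest mean of the lists, 66.2% ± 5.24 (n = 1219). Their difference from the intergenic background of 68.0% was -1.81 points (n = 1219, adjusted p = 0.0002 for each list). For Orc1 the direction turned with a window of 500 bp, 0.48 points above the background (n = 1219, adjusted p = 0.0002), and against whole chromosomes, 2.31 points above (adjusted p = 0.000267).

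Genes of the stress response and of carbon metabolism stood out at Atf1 and Pcr1 peaks. Atf1 had a summit in the promoter window of 12 of 15 stress response genes (80.0%), against 26.7% of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 0.000159). Pcr1 had a summit at 11 of 15 (exact test, adjusted p = 0.000159). The highest were pyp2, a phosphatase of the Sty1 kinase (Atf1 4.94-fold, Pcr1 6.14-fold), srk1 (4.88-fold and 6.45-fold), tpx1, a peroxiredoxin gene (4.86-fold and 6.08-fold), and tps1, which makes trehalose phosphate (4.51-fold and 5.55-fold). Deb1 had a summit at 5 of the 15 (exact test, adjusted p = 0.0107), with cta3 at 6.10-fold, pyp2 at 5.99-fold, tps1 at 4.58-fold and the catalase gene ctt1 at 3.53-fold. Of 15 genes of glucose and carbon metabolism, Atf1 and Pcr1 each had a summit at 12 (exact test, adjusted p = 0.000159 and 1.78e-05). The highest were gld1, a glycerol dehydrogenase gene (4.84-fold and 5.98-fold), the hexokinase gene hxk2 (4.69-fold and 5.87-fold), and the hexose transporter genes ght3 (4.77-fold and 5.55-fold) and ght8 (4.36-fold and 5.57-fold). Deb1 had a summit at 4 (exact test, adjusted p = 0.0448), namely adh4 (4.99-fold), pyk1 (4.97-fold), ght3 (2.32-fold) and hxk2 (2.08-fold). The Deb1 summit counted for hxk2 lay in coding sequence, and the nearest start was that of mug114, 264 bp away. Orc1 did not pass for stress response genes (4 of 15, exact test, adjusted p = 0.546), where hsp9 (3.99-fold), wis1, pyp1 and gst2 had its summits, or for carbon metabolism (2 of 15, ght3 and inv1). The carbon metabolism calls ended with a window of 500 bp upstream, where the ratio for Atf1 was 0.994 and for Pcr1 1.27 (exact test, adjusted p = 1.0 for each) and no gene held a Deb1 summit. So did the stress response call of Deb1 (ratio 3.98, exact test, adjusted p = 0.129), and the carbon metabolism call of Deb1 also ended when each summit counted only for the nearest start (adjusted p = 0.152).

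Several smaller lists also had more summits than other genes. Histone genes held Atf1 and Pcr1 summits at 6 of 8 members each (adjusted p = 0.0248 and 0.00898, Fisher's exact test), led by the divergent pair hta1 and htb1 (4.55-fold for Atf1, 4.76-fold for Pcr1), the histone H2A and H2B genes. Behind the 6 genes lay 5 distinct Atf1 and 4 distinct Pcr1 peaks. Atf1 summits were at 6 of 9 genes of the G1 to S transition (adjusted p = 0.0448, Fisher's exact test), with mik1 at 2.83-fold, cdc22 at 2.21-fold, cdt1 at 2.17-fold and cig2 at 2.11-fold. Pcr1 summits were at 7 of 12 genes of iron and phosphate uptake, with 5 distinct peaks (exact test, adjusted p = 0.0237). The siderophore genes sib1 and sib2 (3.62-fold) and the iron transport genes fio1 and fip1 (3.58-fold) came first. For Atf1 the same number of genes gave an adjusted p of 0.0534 (exact test), and 0.0418 at a −log10 q of at least 10. Pcr1 summits were at 8 of 16 wtf genes, which belong to a multigene family of similar sequence (exact test, adjusted p = 0.0367), with wtf13 at 3.57-fold, wtf14 at 2.52-fold, wtf4 at 2.41-fold and wtf18 at 2.26-fold. Without repeats and chromosome ends, or with a window of 500 bp upstream, that call ended (exact test, adjusted p = 0.274 and 0.107). Orc1 summits were at 5 of 10 flocculation genes (exact test, adjusted p = 0.0392), among them gsf2 (3.05-fold), pfl3 (2.89-fold), pfl2 (2.79-fold) and pfl9 (2.26-fold). When each summit counted only for the gene with the nearest start, the histone calls ended (exact test, adjusted p = 0.714 for Atf1, 0.32 for Pcr1), as did the G1 to S call (0.0966) and the wtf call (0.651). At a −log10 q of at least 10 the G1 to S, iron and wtf calls ended (exact test, adjusted p = 1.0, 0.08 and 1.0).

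The tRNA genes, which are transcribed by RNA polymerase III, held summits of all 4 proteins more often than other non-coding genes. Of 155 tRNA genes, 126 (81.3%) had an Orc1 summit in the promoter window, 103 (66.5%) a Pcr1, 90 (58.1%) an Atf1 and 37 (23.9%) a Deb1 summit, against 15.8%, 14.8%, 18.2% and 3.56% of other non-coding genes (exact test, adjusted p = 4.09e-68, 8.2e-45, 2.82e-26 and 3.86e-18). The highest folds were at SPCTRNAALA.12, SPCTRNASER.09 and SPCTRNAVAL.12 for Orc1 (1 shared peak, 5.26-fold), at SPCTRNAHIS.04 for Pcr1 (6.60-fold, the peak that lies upstream of gut2), at SPBTRNAGLU.05 for Atf1 (4.54-fold) and at SPCTRNAGLY.10 for Deb1 (6.75-fold). Many tRNA genes exist in several near-identical copies, so that the place of a single peak among copies is uncertain and these p-values are too small. The genes held 104 distinct Orc1, 83 Pcr1, 74 Atf1 and 28 Deb1 peaks. Background of the FLAG precipitation common to all 4 lists was not tested here, since the untagged sample is not analysed as a list.

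No list passed for sexual differentiation, heterochromatin factors, replication proteins or ribosomal proteins. Of 17 genes of sexual differentiation and meiosis, 5 had an Atf1 and 6 a Pcr1 summit (exact test, adjusted p = 0.977 and 0.476), the highest at ste6 (4.83-fold and 4.48-fold) and rec12 (2.92-fold and 3.16-fold), where both summits lay inside the tRNA gene SPATRNAILE.01. Of 18 genes of heterochromatin factors, 4 had an Atf1 and 5 a Pcr1 summit (exact test, adjusted p = 0.977 and 0.875). The gene raf2, a subunit of the histone methyltransferase complex, had peaks of Atf1 (3.22-fold), Pcr1 (3.45-fold) and Deb1 (5.40-fold), and swi6, the HP1 homologue, had in its promoter window an Orc1 summit (3.32-fold) that lay inside the tRNA gene SPATRNALYS.01. Among 14 genes of replication proteins, sld3 had the highest Atf1 (4.92-fold) and Pcr1 (5.46-fold) summits and orc4 the only Orc1 summit (1.77-fold). Ribosomal protein genes held an Atf1 summit at 40 of 114 (35.1%, exact test, adjusted p = 0.128), led by rpl4102 (3.79-fold), which also had a Deb1 summit of 6.76-fold. The Atf1 call for ribosomal proteins was gained with a window of 500 bp upstream (ratio 1.55, exact test, adjusted p = 0.0298). At a −log10 q of at least 10 the direction turned for Atf1 (ratio 0.474, exact test, adjusted p = 0.08) and Pcr1 (ratio 0.243, 0.0137).

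Of the genes of the mapped proteins, pcr1 had summits of Atf1 (4.65-fold), Pcr1 (4.69-fold) and Orc1 (2.72-fold) in its promoter window, and atf1 had all 4, as given above. No summit lay in the windows of deb1, orc3 or orc5, and orc1, orc2 and orc6 lie on the part of chromosome 2 that was not annotated here.

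**Figure D4:**
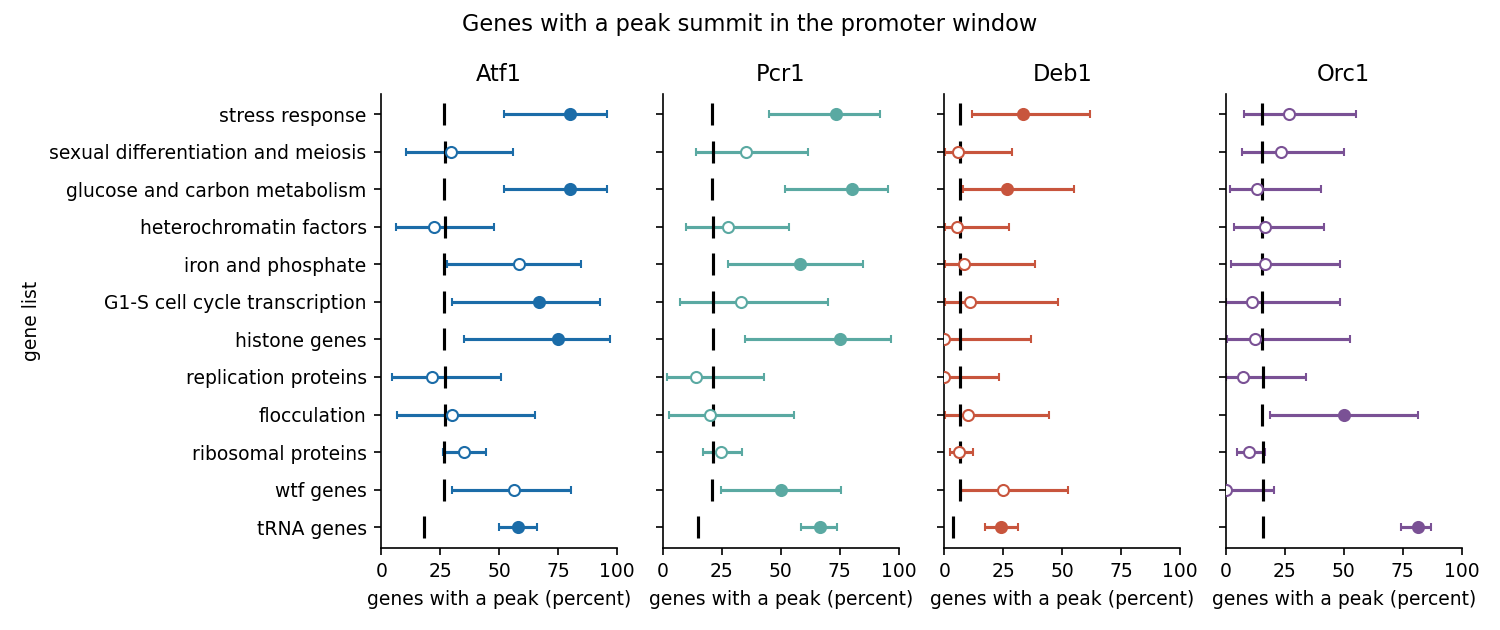
Percent of genes with a peak summit in the promoter window (horizontal axis, 0 to 100) for 12 gene lists (vertical axis) and the 4 proteins (panels). Circles are the shares with exact 95% binomial intervals, filled where the adjusted p was under 0.05, and black ticks are the shares of the other genes; stress response genes reached 80.0% for Atf1 and tRNA genes 81.3% for Orc1.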

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

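Interval midpoints, summits inside their interval only, placement on the annotated part and, for motif, words, AT content and gene lists, the removal of repeats were chosen after the data were seen; the other alternatives were planned. Of 48 alternatives for the overlaps of lists, 48 kept direction and threshold, with ratios of 1.13 to 21.0, as did 5 of 5 for the places of all 4 proteins and 24 of 24 for positions. The motif kept its call in 28 of 32 and AT content in 22 of 24. Of 8 alternatives for the Deb1 word, 5 passed with repeats included, where copies make p-values too small. Tested without repeats GGTAACA passed, and searched without them an unrelated word, TCCCGAA, did (3 of 76 summits). GGTAACA and AGGTAAC were among the next words of that search. Gene lists with a call kept it in 62 of 76, and 27 of all 48 pairs of list and protein had a call in no setting.

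At a −log10 q of at least 10 there were 758 Atf1, 630 Pcr1 and 871 Orc1 peaks, with 5, 4 and 7 in the mating-type region. A fold of at least 3 left 416, 447 and 279 peaks of these lists. Without chromosome ends and the repeats of the annotated part there were 208 Deb1 peaks. These settings remove peaks by construction. The motif ratio of Deb1 was 1.82 within 50 bp, that of Orc1 1.87 with the palindrome, 1.00 within 250 bp and 1.07 at the stricter q, none past the threshold; the word ratio was 2.29 with summits inside only. Orc1 AT content turned to 0.48 and 2.31 points above background with 500 bp and whole chromosomes. Gene list ratios turned for carbon metabolism with 500 bp (Atf1 0.994, Deb1 0), at the stricter q for G1 to S (Atf1 0.870), ribosomal proteins (Atf1 0.474, Pcr1 0.243) and wtf genes (Pcr1 0.588), and without repeats for wtf genes (Atf1, Pcr1 and Deb1 0), where the setting removes the peaks in repeats. Otherwise the cause was not tested. Of the other gene list changes, 9 lost a call and 8 gained one, the latter among the 5 pairs that passed only in some alternative.

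No paired analysis was possible because each protein has 1 list; no replicate was left out for the same reason. Merging changed no number, since no records overlapped, and the tRNA list without repeats cannot give a value. Depth is unknown, so a missing peak is no sign of absence.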

Other observations

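The tests in this part were chosen only after the results were seen, except the overlap of Deb1 with Atf1 peaks without repeats and with intergenic placement. Deb1 peaks touched all 12 Tf2 retrotransposon genes of the annotated part, among them Tf2-1 (6.26-fold), Tf2-6 (5.79-fold) and Tf2-10 (5.15-fold), 8.52 times the number at random placement. Some of these genes had been seen among the highest Deb1 peaks, and copies are not independent, so no p-value is given for the repeat counts of this paragraph. The Atf1, Pcr1 and Orc1 lists touched 1, 2 and 0. Of 201 long terminal repeats, Deb1 peaks touched 105 (52.2%, ratio 20.5), Atf1 140 (69.7%, ratio 6.45), Pcr1 122 (60.7%, ratio 7.30) and Orc1 30 (14.9%, ratio 1.71). Of 155 tRNA genes, Orc1 peaks touched 133 (ratio 13.6), Pcr1 88 (ratio 10.4), Atf1 75 (ratio 6.69) and Deb1 30 (ratio 11.5), and all 30 with Deb1 also had Orc1; 16 had all 4 proteins and 13 had none. Of 39 rRNA genes, Orc1 peaks touched 33 (ratio 7.74), Atf1 13 (ratio 2.42), Deb1 8 (ratio 5.39) and Pcr1 8 (ratio 1.84). Which of several near-identical copies gave a peak is uncertain. All ratios of this paragraph come from placement anywhere on a chromosome. Intergenic placement was not tried for these features, so the preference of peaks for intergenic sequence may make up part of each ratio.

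The word AGGTAAC stood in 147 of 296 Deb1 intervals (49.7%), against 5.08% of random intervals, and in 59 of 166 that touch no repeat (35.5%, ratio 7.11). The word was chosen on some of these same peaks, so no test is given. For the next shares the whole core TGACGT had to lie within 100 bp of the summit. That counts slightly fewer summits than the rule used above, which took its centre. The ATF/CRE core stood near 11.7% of Atf1 peaks with a Deb1 peak and 16.4% of those without (Fisher's exact test, adjusted p = 0.117), and near 12.2% and 14.5% of Pcr1 peaks (adjusted p = 0.547). In the highest of 4 bins of Atf1 peaks by fold, it stood near 17.5% of those with a Deb1 peak and 37.7% of those without. Copies of repeats among these peaks are not independent, so no p-value is given for this difference. Among the Atf1 peaks of this bin touching no repeat the shares were 27.1% and 39.3% (Fisher's exact test, adjusted p = 0.117).

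Deb1 peaks that overlap an Orc1 peak held AGGTAAC less often, in 19 of 98 (19.4%) against 128 of 198 without Orc1 (64.6%). With and without an Atf1 peak the shares were 49.3% and 50.6%. Copies of repeats among these peaks are not independent, so no p-value is given for these shares. Repeated sequence as the whole cause is argued against by a difference of -35.4 points among peaks touching no repeat (Fisher's exact test, adjusted p = 1.29e-05). Low fold as the whole cause is argued against by -45.2 points among Deb1 peaks above the median fold, 12 of 36 with Orc1 against 88 of 112 without. These peaks include copies of repeats, so no p-value is given, and low fold together with repeats was not tested. Deb1 signal at Orc1 places may thus have a source other than the word, for which background of unlike strength between lists stays open. No biological explanation was tested, since no group of samples bears on it.

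Deb1 peaks at long terminal repeats could come from reads shared between copies. A rise of all repeats alike in every list is argued against by the Orc1 ratio of 1.71, which is 1 list only. Atf1 and Pcr1 peaks touched 69.7% and 60.7% of these repeats, more than the 52.2% of Deb1. A rise shared by these 3 lists stays open. Of repeats with few words elsewhere, 22 of 82 (26.8%) were touched, and of the others 83 of 119 (69.7%). The share at random, 2.55%, was computed for all 201 repeats with peaks placed anywhere on a chromosome. It was not computed for these 82 or for intergenic placement. Whether spread from a few copies is the whole cause is thus not decided. On chromosomes 2 and 3, 41 of 47 repeats with AGGTAAC and 14 of 64 without it were touched, but many share sequence with other places. Among those with few words elsewhere the numbers were 2 of 6 and 7 of 39 (Fisher's exact p = 0.583), too few to tell the word from the likeness of copies, so both stay open. No biological explanation was tested.

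Atf1 peaks at Deb1 peaks may reflect common background. Repeats as the whole cause are argued against by a ratio of 7.20 without them, and a preference for intergenic sequence by a ratio of 2.41. With equal numbers of peaks, 238 Deb1 peaks overlapped 1 of the 1526 highest Atf1 peaks and 115 an Orc1 peak. Copies of repeats among these peaks are not independent, so no p-value is given. Equal numbers of peaks need not hold equal numbers of background peaks, so this comparison cannot decide on background alike in all lists. Background, alike in all lists or differing between them, stays open, since the untagged sample is not analysed here as a list. No biological explanation was tested, since no group of samples bears on it.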
